A study of Mus musculus with 69 samples.

How the data were processed

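RNA was extracted from mouse hearts with RNeasy Plus kits, checked by Bioanalyzer and NanoDrop, and 100 ng per sample was made into biotin-labelled cRNA with a 3' IVT kit for Affymetrix HT MG-430 PM arrays, per the labels. Each array was treated as a separate mouse. The deposited table holds log2 signals, already summarised per probe set and normalized between arrays by the authors, who name MAS5 in their processing notes without a version or a role. The log2 unit was read from the values, which run from 1.83 to 13.94, and from the hybridization spike-ins, where cre lies 5.09 above bioB. The 37 injection arrays share a distribution of values and the 32 inhalation arrays another, with median 95th percentiles of 9.25 and 9.52, so that the arms appear to have been normalized as 2 sets and levels were compared only within a route. Scan dates and batches are not given in the sources used here.

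There are 45141 probe sets in it, of which 104 are AFFX controls, 28898 carry a single gene symbol, 551 several and 15588 none. Probe sets were tested where at least 1 group mean lay above the median of all group means (3.23), which kept 26773. In R 4.3.3, with tables read by the data.table package (version 1.17.8), limma 3.58.1 fitted a mean per group (18 groups, 51 residual degrees of freedom) with eBayes and an intensity trend (5.53 prior degrees of freedom). Contrasts were each cyanide group against its control, the average of these over the times of a route, and the difference between the routes at each shared time, all two-sided; F tests compared the control groups over time within each route. P values were adjusted by Benjamini-Hochberg within each contrast and called at an adjusted p of 0.05. Probe sets without a symbol were tested and counted but not named.

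Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 36 lists of a contrast. They were 22 lists of pathways and 14 of cell type markers, each gene represented by its probe set of highest mean. The lists cover hypoxia, glycolysis, immediate early genes, the integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2, glucocorticoid response, fatty acid oxidation, cytochrome c oxidase, the other respiratory complexes, the citric acid cycle, cyanide detoxification, inflammation, interferon response, cardiac stress, ion channels, p53, cell cycle, matrix, circadian clock and proteasome. The markers cover atrial and ventricular cardiomyocytes, fibroblasts, endothelium, smooth muscle, macrophages, neutrophils, lymphocytes, thymocytes, erythroid cells, adipocytes, skeletal muscle, lung epithelium and Schwann cells. Some genes are in more than 1 list, such as Nfkbia in the glucocorticoid and NF-kB lists. The groups, contrasts, lists, the rule for named genes and the alternatives not marked below as added were set before the data were examined. That rule takes, per contrast, the 12 largest rises and 12 largest falls among called probe sets with 1 symbol and every exposed array on the same side of the control mean, with 1 probe set per gene, up to 4 members of each list by lowest p, and a fixed set of 24 genes. The genes named in the text are a part of those, chosen after their values were seen. A gene result counted among the alternatives is not reported here.

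RNA quality was measured by the log2 ratio of the 3' to the 5' control probe sets of actin and Gapdh and by the 18S ribosomal control, and compared by exact permutation tests, two-sided, adjusted over the 9 comparisons. With 4 against 4 arrays the smallest such p is 0.0286, and with 3 against 3 it is 0.1. The overlap of the routes was tested by Fisher's exact test. The procedure was tested on simulated data with the group sizes and the residual spread of each probe set. Of 2-fold changes 92% were recovered at KCN 1 h, 88% at KCN 4 h, 88% at HCN 2 h and 66% for the difference at 1 h. Of 1.5-fold changes these were 52%, 46%, 62% and 18%. False calls were 5.52%, 7.43%, 5.43% and 6.71% of the calls. The simulated noise was independent between probe sets and had the same spread in all groups. It held no variation shared by the probe sets of an array, so these rates need not apply to the real arrays.

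The alternatives tried were quantile normalization and median centring between arrays, no filter and a stricter one, eBayes without the trend, the replicate number as a block, separate fits per route and of only the groups compared, adjustment over the 9 contrasts together, a minimum of 1.5-fold, other probe sets for the lists, and leaving out each array in turn. An alternative without an offset was not run, since the values were already on the log2 scale. Added after the data were seen were the actin ratio as a covariate, the level of the airway transcripts Scgb1a1 and Bpifa1 as a covariate, leaving out the 2 HCN 2 h arrays of highest actin ratio, 1 probe set per gene, and 1 to 5 within-gene factors as covariates. The within-gene factors are principal components of 7493 differences between probe sets of the same gene, with route means removed; the first and the second hold 20.4% and 13% of the variance. The number 2 was picked for comparisons of shared genes after the counts with 0 to 5 had been seen, so all of 1 to 5 are reported. The factors differed between some groups, such as the first at 0.0712 to 0.326 in HCN 24 h and -0.153 to -0.127 in air 24 h. A count with them can therefore lose true changes as well as false ones.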

Results

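RNA from the hearts of adult male CD-1 mice weighing 20 to 35 g was profiled on Affymetrix expression arrays after exposure to cyanide by 1 of 2 routes. Potassium cyanide (KCN) was injected under the skin at 8.0 mg/kg, with volume-matched saline as the control, and hearts were taken at 1, 2, 4, 8 and 24 h. Hydrogen cyanide (HCN) was inhaled nose-only at 327 ppm, with air as the control, and hearts were taken at 1, 2, 4 and 24 h. Cyanide blocks cytochrome c oxidase, the last enzyme of the respiratory chain, and the heart depends on respiration for its energy. There were 69 arrays in 18 groups, 37 from the injection arm and 32 from the inhalation arm. Each group held 4 arrays except saline 2 h, saline 4 h and KCN 4 h, which held 3 each. Of 45141 probe sets, 26773 were bright enough to be tested, and 19929 of these carried a single gene symbol, for 12436 genes. Arrays correlated with one another at 0.968 to 0.995 across probe sets. Their number limits the precision. Gene values are the log2 change ± SE from limma with n = 4 against 4 unless stated. Group levels are the mean log2 signal ± SD, and "rose" or "fell" is used of what passed an adjusted p of 0.05. Each gene value comes from 1 probe set, which for a gene such as Ccn1 or Fam107a can differ between comparisons. Where a control level lies near or below the filter threshold of 3.23, as for Cxcl1, the size of a rise is uncertain and may be a lower bound.

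Each cyanide group was compared with its control at the same time, which asks what each route of exposure changed in the heart and when. The counts of changed probe sets after KCN were 1094 at 1 h, 1765 at 2 h, 605 at 4 h, 90 at 8 h and 3191 at 24 h. After HCN they were 718 at 1 h, 6763 at 2 h, 1967 at 4 h and 3834 at 24 h. Immediate early genes had their highest median changes at 1 h by both routes, 1.01 after KCN and 1.77 after HCN, where the counts were lower than at 2 h. The large counts at HCN 2 h, HCN 24 h and KCN 24 h came with groups that differed in a measure of RNA quality, the log2 ratio of the 3' to the 5' actin control probe set. That ratio was 1.22 ± 0.61 (SD) at HCN 2 h against 0.452 ± 0.143 in air. It was 0.979 ± 0.255 at HCN 24 h against 0.386 ± 0.045 in air, and 0.473 ± 0.131 at KCN 24 h against 0.879 ± 0.0907 in saline.

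**Figure D1:**
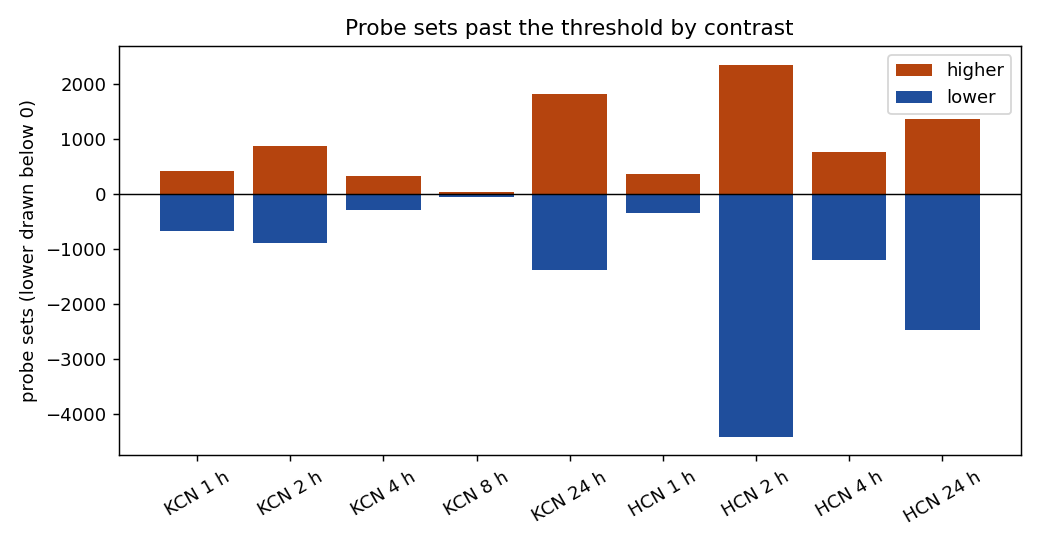
Number of probe sets with an adjusted p under 0.05 in each of the 9 comparisons of cyanide with its control, with probe sets higher after cyanide drawn above 0 and lower ones below 0. The counts ranged from 90 at KCN 8 h to 6763 at HCN 2 h.

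In KCN against saline at 1 h, genes that cells switch on within minutes of a stimulus rose together. Of 26 measured immediate early genes 14 rose and 0 fell, 21 and 0 adjusted over the list alone, with a median log2 change of 1.01 (camera adjusted p = 6.19e-24; adjusted p = 0.0027 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 3.30 ± 0.41, from 7.23 ± 0.81 (SD) in saline to 10.53 ± 0.32. The transcription factors Fos, Egr1 and Egr2 rose by 2.66 ± 0.61, 2.46 ± 0.41 and 2.39 ± 0.31. Ccn1, a secreted matrix protein, rose by 2.54 ± 0.31. Gadd45b and Gadd45g, which encode sensors of cell stress, rose by 2.40 ± 0.27 and 1.96 ± 0.25. Nr4a3, an orphan nuclear receptor, rose by 2.56 ± 0.45 on 1 probe set, while its other probe sets had a median change of 0.36. In the list of inflammatory cytokines and NF-kB targets 4 of 23 members rose, 7 adjusted over the list alone (adjusted p = 0.000184; adjusted p = 0.191 with an estimated correlation). They included the feedback inhibitors Nfkbia (0.90 ± 0.15) and Tnfaip3 (1.05 ± 0.23). Cxcl1, a neutrophil-attracting chemokine, rose by 1.35 ± 0.33, but by 0.66 without KCN 1 h replicate 3, where it no longer passed. Macrophage markers had 2 of 10 members higher, 3 adjusted over the list alone (adjusted p = 0.00155; adjusted p = 0.446 with an estimated correlation). Kcnj11, the pore subunit of the ATP-sensitive potassium channel, fell by 0.88 ± 0.15. Ankrd37, a known target of hypoxia-inducible factor, fell by 1.79 ± 0.27, and the citric acid cycle enzyme citrate synthase (Cs) by 0.23 ± 0.05. The largest falls were on single probe sets of widely expressed genes: Pttg1ip fell by 3.09 ± 0.26, Ndufab1, a subunit of respiratory complex I, by 2.98 ± 0.29 and Rab2a, a vesicle transport protein, by 2.42 ± 0.25. Their other probe sets had median changes of -0.09, -0.03 and 0.02. The actin 3' to 5' ratio was 0.48 ± 0.08 in these KCN arrays and 0.841 ± 0.172 in saline (exact permutation p = 0.0286, the smallest 4 against 4 can give; 0.0858 adjusted over the 9 comparisons). Transcripts of airway epithelium were also higher. Scgb1a1, the secretoglobin of club cells, read 11.41 ± 0.42 in KCN and 2.91 ± 0.25 in saline, a change of 8.50. That change stayed at 8.307 to 8.64 but no longer passed whichever of the 8 arrays was left out. The saline level lay below the filter threshold of 3.23, so the change may be a lower bound. Of 5 lung epithelium markers, Scgb1a1 included, 1 rose, 3 adjusted over the list alone (adjusted p = 0.00973; adjusted p = 0.554 with an estimated correlation, and 0.173 without KCN 1 h replicate 4). In all, 419 probe sets rose (317 genes) and 675 fell (446 genes), 475 by at least 1.5-fold. The count was 573 without saline 1 h replicate 2, 579 without KCN 1 h replicate 2 and 729 without KCN 1 h replicate 3. It was 424, 313 and 193 with 3, 4 and 5 within-gene factors as covariates.

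**Figure D2:**
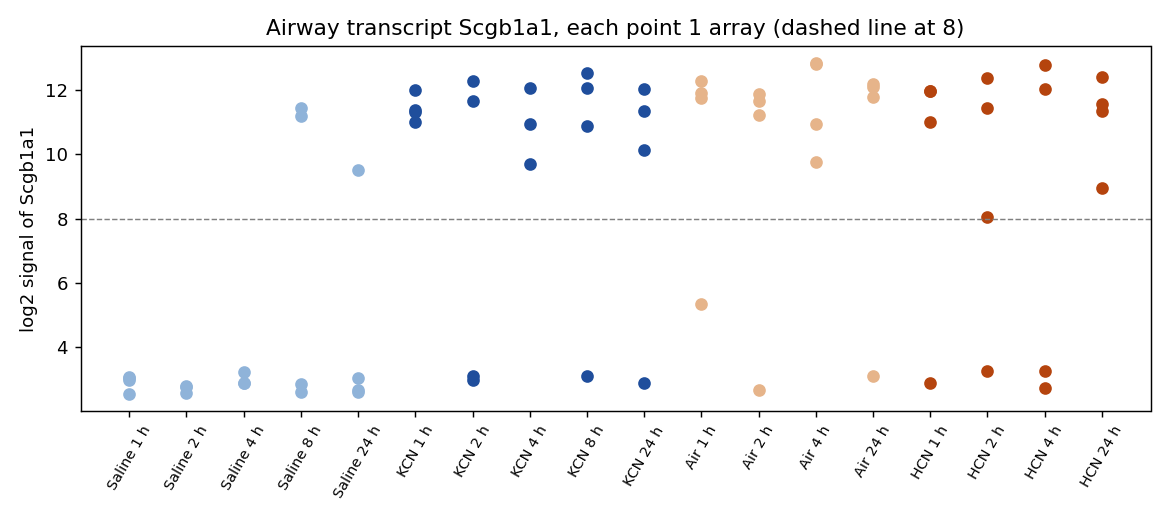
Log2 signal of Scgb1a1, a transcript of airway epithelium, on each array by group, with a dashed line at 8. None of the 10 saline arrays at 1, 2 and 4 h lay above the line, and all 4 KCN arrays at 1 h did. In all, 3 of 18 saline, 15 of 19 KCN, 13 of 16 air and 12 of 16 HCN arrays did.

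In KCN against saline at 2 h, glucocorticoid-responsive genes rose: 9 of 19 rose and 0 fell, 10 and 0 adjusted over the list alone (median 0.78; adjusted p = 5.06e-13; adjusted p = 0.0416 with an estimated correlation). The comparison holds 4 KCN and 3 saline arrays. Ddit4, an inhibitor of mTOR signalling, rose by 1.42 ± 0.29, and Cebpd, a transcription factor of the acute phase, by 1.04 ± 0.24. Fam107a, a small actin-binding protein, rose by 1.499 ± 0.36, with a median of 1.19 on its other probe sets. Immediate early genes moved both ways, with 7 of 26 higher and 2 lower in both counts, over all probe sets and adjusted over the list alone (adjusted p = 0.000328; adjusted p = 0.55 with an estimated correlation). Atf3 rose by 2.87 ± 0.44, Nr4a3 by 3.25 ± 0.49 and Ccn2, a matrix growth factor, by 1.31 ± 0.23, while Jun fell by 1.15 ± 0.24. Of NF-kB targets 2 of 23 rose, and 2 adjusted over the list alone (adjusted p = 0.000546; adjusted p = 0.304 with an estimated correlation), with Nfkbia at 0.99 ± 0.16. Of p53 targets 4 of 17 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.0143; adjusted p = 0.0416 with an estimated correlation), including Gadd45b (1.28 ± 0.29) and Gadd45g (1.05 ± 0.27). The list no longer passed without saline 2 h replicate 2 (0.0534) or KCN 2 h replicate 2 (0.0519). Gp9, a subunit of the von Willebrand factor receptor, fell by 2.08 ± 0.38, from 6.20 ± 0.93 (SD) in saline to 4.12 ± 0.37, and Treml1, a receptor of platelet granules, by 1.77 ± 0.23. Filip1, which binds filamin, rose by 2.45 ± 0.34 and Sppl2a, an intramembrane protease, by 1.93 ± 0.17, with 0.57 and 0.18 as the medians of their other probe sets. Adipocyte markers were higher as a list with 0 of 5 past the test, 3 adjusted over the list alone (adjusted p = 0.00392; adjusted p = 0.55 with an estimated correlation, and 0.0844 without KCN 2 h replicate 2). Cell cycle genes were lower as a list with 0 of 18 past the test by limma, in either count (adjusted p = 0.017; adjusted p = 0.927 with an estimated correlation). Without saline 2 h replicate 3 the direction turned (0.931), and without KCN 2 h replicate 2 it was 0.122. The signal of the 18S ribosomal control was 13.00 ± 0.08 in KCN and 11.80 ± 0.23 in saline, the lowest mean of all groups. In all, 882 probe sets rose (516 genes) and 883 fell (695 genes), 1140 by at least 1.5-fold. The count was 1065 without saline 2 h replicate 3 and 871 without KCN 2 h replicate 4. It was 133, 50, 67 and 64 with 2 to 5 within-gene factors, 918 with the replicate block and 544 in a fit of these groups alone.

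In KCN against saline at 4 h, with 3 arrays per group, Nr4a3 rose by 3.15 ± 0.52, from 6.65 ± 0.79 (SD) to 9.80 ± 0.49, and the kinase Mapkapk3 and hexokinase 1 (Hk1), which starts glycolysis, fell by 0.93 ± 0.14 and 0.92 ± 0.16. These 3 passed whichever array was left out. In a fit of these groups alone Mapkapk3 and Hk1, with log2 changes of -0.93 and -0.92 as before, no longer passed. With 5 within-gene factors none of the 3 did, at 2.700 for Nr4a3, KCN against saline at 4 h, -0.7027 for Mapkapk3, KCN against saline at 4 h, and -0.515 for Hk1, KCN against saline at 4 h. Glucocorticoid-responsive genes had 1 of 19 members higher, 5 adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.69 with an estimated correlation), and immediate early genes 3 of 26 in both counts (adjusted p = 0.00403; adjusted p = 0.692 with an estimated correlation). Both list calls were lost without KCN 4 h replicate 2, at 0.454 and 0.0972. Atf3 rose by 2.04 ± 0.47, and by 1.87 without saline 4 h replicate 1 and 1.28 without KCN 4 h replicate 2, where it no longer passed. Macrophage markers had 1 of 10 higher, 6 adjusted over the list alone, with a median of 0.46 (adjusted p = 0.0025; adjusted p = 0.69 with an estimated correlation). In ion channels and calcium handling, KCN against saline at 4 h, 0 of 14 members passed in either count and the list was lower (adjusted p = 0.0348; adjusted p = 0.69 with an estimated correlation). That call was lost without saline 4 h replicate 1 (0.0637), saline replicate 2 (0.0882), KCN replicate 1 (0.13) or KCN replicate 2 (0.149). In all, 325 probe sets rose (212 genes) and 280 fell (214 genes), 343 by at least 1.5-fold. Scgb1a1 read 9.69 to 12.07 in the 3 KCN arrays and 2.88 to 3.22 in the 3 saline arrays, and the count of 605 was 229 with the level of airway transcripts as a covariate. Quantile normalization changed the share that rose from 53.7% to 38.1% of a count of 916. The count was 171, 125 and 947 without saline replicates 1, 2 and 3, and 231 and 56 without KCN replicates 1 and 2. It was 29 in a fit of these groups alone and 13 with 5 within-gene factors.

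In KCN against saline at 8 h, genes of mitochondrial respiration were slightly lower as groups. These were 3 of the 5 lists that passed, and the other 2 were higher. Among the 41 measured genes of respiratory complexes I, II, III and ATP synthase the median log2 change was -0.08, with 0 higher and 1 lower, 1 and 7 adjusted over the list alone (adjusted p = 7.53e-06; adjusted p = 0.442 with an estimated correlation). Citric acid cycle enzymes had a median of -0.09 with 1 of 15 lower in both counts (adjusted p = 0.00983; adjusted p = 0.442 with an estimated correlation). Cytochrome c oxidase subunits, the enzyme that cyanide blocks, had a median of -0.08 with 0 of 19 past the test and 2 lower adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.342 with an estimated correlation). That call was lost without KCN 8 h replicate 2 (0.0599) or replicate 4 (0.0814). Nr4a3 rose by 2.80 ± 0.45, from 4.73 ± 0.77 (SD) to 7.54 ± 1.12, and passed whichever array was left out. Agt, the precursor of angiotensin, rose by 1.74 ± 0.32, and by 1.497 without saline 8 h replicate 1 and 1.68 without KCN 8 h replicate 2, where it no longer passed. In all, 37 probe sets rose (31 genes) and 53 fell (44 genes), 48 by at least 1.5-fold. Centring each array on its median changed the share that rose from 41.1% to 29.3%. The count was 18 and 37 without saline replicates 1 and 2, and 3, 223 and 202 without KCN replicates 2, 3 and 4. Limma on these groups alone called 0, with 1768 at an unadjusted p under 0.05.

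In KCN against saline at 24 h, glycolysis enzymes and matrix genes were higher. Of 13 glycolysis enzymes 6 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.19; adjusted p = 0.0236; adjusted p = 0.852 with an estimated correlation). Pyruvate kinase (Pkm) rose by 0.64 ± 0.12, from 9.93 ± 0.09 (SD) to 10.58 ± 0.11, and aldolase A (Aldoa) by 0.38 ± 0.07. Of 15 genes of extracellular matrix and fibrosis 4 rose and 0 fell, 6 and 0 adjusted over the list alone (median 0.31; adjusted p = 0.0236; adjusted p = 0.852 with an estimated correlation). They included the gelatinase Mmp2 (0.71 ± 0.15) and the collagen Col3a1 (0.51 ± 0.11). Both list calls were lost without saline 24 h replicate 1, at 0.0664 each, and without KCN 24 h replicate 2, at 0.0793 for glycolysis and 0.0863 for matrix. With the actin ratio as a covariate the camera adjusted p was 0.277 for glycolysis and 0.0133 for matrix genes. With 2 within-gene factors it was 0.757 and 0.0993, so only the matrix call with the actin ratio held. The direction turned for matrix genes with 3 to 5 factors. Tst (rhodanese) and Mpst, the sulfurtransferases that turn cyanide into thiocyanate, rose by 1.10 ± 0.25 and 0.67 ± 0.13 in the fit without covariates. Of 16 gene results at KCN 24 h, 15 kept their call with the actin ratio as a covariate. With 2 within-gene factors 6 did, and at every number of factors 3. Lipe, a lipase, rose by 1.85 ± 0.32 and the enzyme Cyp2e1 by 2.48 ± 0.64. Of 5 adipocyte markers 0 rose, 4 over the list alone (median 1.41, camera adjusted p = 0.124). The largest falls were again on single probe sets: Ndufab1 fell by 2.83 ± 0.29, Rab2a by 2.73 ± 0.25, Pttg1ip by 2.62 ± 0.26 and Mfn1, a mitochondrial fusion protein, by 2.29 ± 0.26. Their other probe sets had medians of -0.08, -0.26, -0.03 and 0.09. The actin ratio was lower in KCN than in saline by a log2 difference of -0.405 (exact permutation p = 0.0286; 0.0858 adjusted). In all, 1817 probe sets rose (1369 genes) and 1374 fell (854 genes), 1085 by at least 1.5-fold. The count was 1829 without saline 24 h replicate 1 and 2031 without KCN 24 h replicate 1. It was 277, 60, 93 and 66 with 2 to 5 within-gene factors, and of the 277 probe sets 242 were among the 3191.

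In KCN against saline averaged over the 5 times, immediate early genes (13 of 26 higher, 14 adjusted over the list alone, adjusted p = 6.56e-11), glucocorticoid-responsive genes (7 of 19, 13 alone, 3.75e-07) and adipocyte markers (4 of 5, 5 alone, 8.49e-06) were higher. Respiratory complexes were lower (6 of 41, 7 alone, median -0.03, 9.26e-05). The lists that rose had an adjusted p = 0.142 with an estimated correlation, and respiratory complexes 0.318. Nr4a3 rose by 2.41 ± 0.21 and Atf3 by 1.59 ± 0.19 in the average, with n = 19 KCN and 18 saline arrays. Adipoq, the fat hormone adiponectin, rose by 2.27 ± 0.40 and Ucp1, the uncoupling protein of brown fat, by 2.74 ± 0.58. Macrophage markers (4 of 10, 7 alone, adjusted p = 0.000184), matrix genes (3 of 15, 5 alone, 0.000492), lung epithelium markers (3 of 5, 3 alone, 0.00155), NF-kB targets (2 of 23, 1 alone, 0.00258) and genes of the integrated stress response (5 of 20, 5 alone, 0.0182) were also higher. In that order they had an adjusted p = 0.189, 0.318, 0.263, 0.263 and 0.142 with an estimated correlation. Asns, asparagine synthetase, rose by 0.49 ± 0.13 and C1qb, a macrophage marker, by 0.34 ± 0.07. In all, 1357 probe sets rose and 1190 fell, 227 by at least 1.5-fold. The count of 2547 was 1552 with the actin ratio as a covariate and 25, 40 and 31 with 3 to 5 within-gene factors. It was also lower, by more than 1.5 times, with the airway level as a covariate.

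In HCN against air at 1 h, immediate early genes rose in nearly the whole list: 21 of 26 rose and 0 fell, 24 and 0 adjusted over the list alone, with a median of 1.77 (adjusted p = 1.12e-66; adjusted p = 8.32e-08 with an estimated correlation). Fos rose by 4.79 ± 0.61, from 7.17 ± 0.17 (SD) to 11.96 ± 0.19, Egr1 by 4.73 ± 0.41, Atf3 by 4.32 ± 0.41 and Fosb by 4.15 ± 0.26. Fosb read 2.323 to 2.758 in air, below the filter threshold of 3.23, so its rise may be a lower bound. Junb and Ier2, further early response genes, rose by 2.88 ± 0.32 and 2.49 ± 0.22. Ccn1 rose by 3.38 ± 0.31 and Apold1, an early response gene of endothelium, by 4.01 ± 0.43. Of inflammatory cytokines and NF-kB targets 11 of 23 rose and 0 fell, 14 and 0 adjusted over the list alone (adjusted p = 3.91e-23; adjusted p = 8.54e-06 with an estimated correlation). The chemokines Cxcl1 and Cxcl2 rose by 4.53 ± 0.33 and 3.30 ± 0.19, and the inhibitors Nfkbiz and Nfkbia by 3.32 ± 0.27 and 1.27 ± 0.15. Cxcl1 read 3.101 to 3.582 in air, close to the filter threshold of 3.23, so its rise may be a lower bound. Gadd45g and Gadd45b rose by 2.25 ± 0.25 and 1.95 ± 0.27. Ppp1r15a, a phosphatase subunit of the stress response, rose by 1.62 ± 0.21, and Adm, the vasodilator adrenomedullin, by 0.91 ± 0.18. Map3k6 and Zbtb16, both members of the glucocorticoid list, fell by 1.38 ± 0.27 and 1.42 ± 0.31, while Sgk1 and Errfi1 of the same list rose by 1.36 ± 0.21 and 1.94 ± 0.28; the list did not pass. Sox18, an endothelial transcription factor, fell by 1.08 ± 0.20. Fatty acid oxidation genes had a median of -0.17 with 1 of 21 lower, 3 adjusted over the list alone (adjusted p = 0.000762; adjusted p = 0.545 with an estimated correlation, and 0.0504 without air 1 h replicate 2). Respiratory complexes had a median of -0.05 with 1 of 41 lower in both counts (adjusted p = 0.000984; adjusted p = 0.627 with an estimated correlation). Endoplasmic reticulum chaperones were lower and interferon-stimulated genes higher as lists, both with 0 of 17 past the test (adjusted p = 0.01 each; adjusted p = 0.545 and 0.643 with an estimated correlation), with 1 chaperone lower and 0 interferon genes higher adjusted over the list alone. The chaperone call was lost without air 1 h replicate 1 (0.107) and the interferon call without air 1 h replicate 1 (0.0503) or replicate 4 (0.0764). In all, 369 probe sets rose (248 genes) and 349 fell (243 genes), 447 by at least 1.5-fold. The count was 474 without HCN 1 h replicate 4, and 1340 with 4 and 432 with 5 within-gene factors.

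In HCN against air at 2 h, immediate early genes were again higher, together with glucocorticoid-responsive and inflammatory genes. Immediate early genes rose in 16 of 26 members and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 5.73e-14; adjusted p = 0.022 with an estimated correlation). Glucocorticoid-responsive genes rose in 11 of 19, 13 adjusted over the list alone (adjusted p = 9.75e-13; adjusted p = 0.022 with an estimated correlation). NF-kB targets rose in 12 of 23, 13 adjusted over the list alone (adjusted p = 6.3e-11; adjusted p = 0.0102 with an estimated correlation). Atf3 rose by 4.59 ± 0.41, from 6.19 ± 0.48 (SD) to 10.77 ± 0.10, Ptx3, a secreted protein of inflammation, by 3.75 ± 0.34, and Cxcl1 by 2.49 ± 0.33. Otud1, a deubiquitinase, rose by 3.05 ± 0.27, Adamts9, a protease of the matrix, by 2.52 ± 0.29, and Sphk1, which makes sphingosine 1-phosphate, by 2.22 ± 0.32. Of the glucocorticoid list, Cebpd rose by 1.78 ± 0.22, Sgk1 by 1.66 ± 0.21 and Ddit4 by 1.83 ± 0.27. The cytokine inhibitor Socs3 and the adhesion molecule Icam1 rose by 1.88 ± 0.30 and 1.24 ± 0.21. Agt rose by 2.19 ± 0.32, the haem-degrading enzyme Hmox1 by 1.58 ± 0.30, and the actin-binding proteins of muscle Xirp1 and Flnc by 1.42 ± 0.21 and 0.84 ± 0.14. Ankrd37 fell by 2.18 ± 0.27. Glycolysis enzymes fell in 9 of 13 members, 10 lower and 2 higher adjusted over the list alone (median -0.25; adjusted p = 0.00643; adjusted p = 0.518 with an estimated correlation), with Gapdh at a log2 change of -0.32 ± 0.05. The list call was lost without HCN 2 h replicate 2 (0.0785), and the direction turned for the list with 2 to 5 within-gene factors and for Gapdh with 3 to 5. Matrix genes rose in 3 of 15 members in both counts (adjusted p = 0.00643; adjusted p = 0.686 with an estimated correlation), a direction that turned with 4 factors. Some of the largest falls were on single probe sets. Akt1, a growth kinase, fell by 2.07 ± 0.35, Kcnip2, a subunit of a potassium channel, by 2.17 ± 0.44 and Klc1, a kinesin light chain, by 2.06 ± 0.31. They had medians of -0.04, -0.09 and -0.09 on their other probe sets and SDs of 1.35, 2.01 and 1.23 among the HCN arrays. The direction turned for Kcnip2 with 2 to 5 factors, for Akt1 with 3 and for Klc1 with 4. The Gapdh 3' to 5' ratio was higher in HCN by 0.531 (exact permutation p = 0.0286, 0.129 adjusted over the 9 comparisons) and the actin ratio by 0.768 (0.0571, 0.128 adjusted). In all, 2354 probe sets rose (1316 genes) and 4409 fell (3206 genes), 2787 by at least 1.5-fold. Quantile normalization changed the share that rose from 34.8% to 45.9%. The count of 6763 was 3016 with the actin ratio as a covariate, 3278 without the 2 HCN arrays of highest ratio, 1934 in a fit of these groups alone. It was 955, 7, 14 and 23 with 2 to 5 within-gene factors. Of 25 gene results at HCN 2 h, 19 kept their call with 2 factors and 0 with 3, 4 or 5, where Atf3, HCN against air at 2 h, was 3.012, 3.191 and 3.026 and Ptx3, HCN against air at 2 h, 3.176, 3.048 and 2.819.

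**Figure D3:**
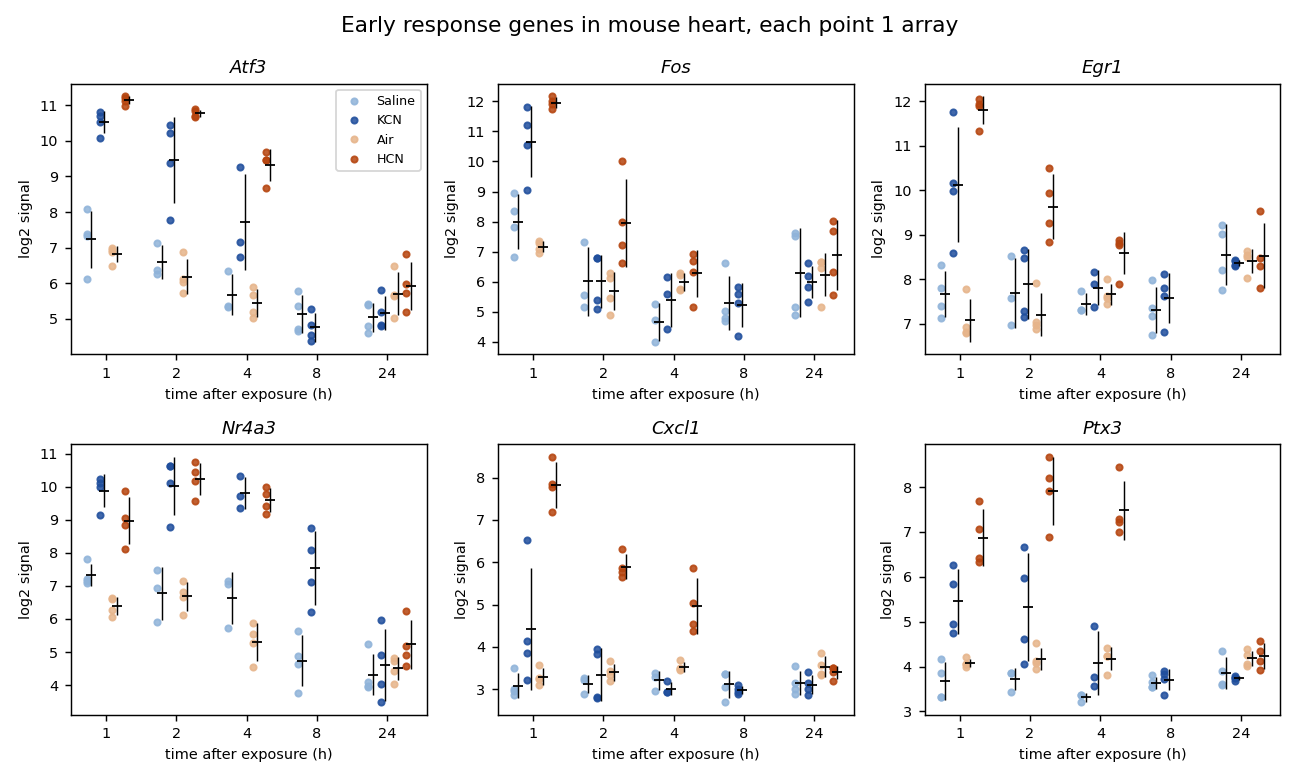
Log2 signal of Atf3, Fos, Egr1, Nr4a3, Cxcl1 and Ptx3 against hours after exposure, with a point per array for saline, KCN, air and HCN, and bars for the mean ± SD. At 1 h Cxcl1 read 7.82 ± 0.54 after HCN and 3.30 ± 0.20 in air, and 4.43 ± 1.44 after KCN and 3.08 ± 0.29 in saline.

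In HCN against air at 4 h, glucocorticoid-responsive genes rose in 18 of 19 members and 0 fell, 19 and 0 adjusted over the list alone, with a median of 1.25 (adjusted p = 1.77e-35; adjusted p = 2.35e-05 with an estimated correlation). Fam107a rose by 3.15 ± 0.34, from 6.46 ± 0.29 (SD) to 9.61 ± 0.62. The stress kinase Map3k6 rose by 2.71 ± 0.27, the transcription factor Zbtb16 by 2.67 ± 0.31 and the receptor chaperone Fkbp5 by 1.76 ± 0.29. Mt1, a metal-binding metallothionein, rose by 0.63 ± 0.12. NF-kB targets rose in 12 of 23 members, 15 adjusted over the list alone (adjusted p = 8.93e-20; adjusted p = 4.14e-05 with an estimated correlation), including Nfkbia (1.16 ± 0.15) and the chemokine Ccl7 (1.66 ± 0.29). The cytokine receptors Osmr and Il1r1 of that list rose by 1.57 ± 0.17 and 1.13 ± 0.19. Neutrophil markers rose in 3 of 9 members, 4 adjusted over the list alone (adjusted p = 0.00137; adjusted p = 0.216 with an estimated correlation). S100a9 rose by 2.62 ± 0.53, S100a8 by 2.61 ± 0.53 and Mmp8, a neutrophil collagenase, by 0.81 ± 0.15. Of p53 targets 6 of 17 rose and 1 fell, 7 and 4 adjusted over the list alone (adjusted p = 0.00132; adjusted p = 0.00299 with an estimated correlation). Among them were the death receptor Fas (1.16 ± 0.23) and Gadd45b (1.45 ± 0.27). Immediate early genes were higher in 6 members and lower in 1, 8 and 1 adjusted over the list alone (adjusted p = 1.23e-06; adjusted p = 0.236 with an estimated correlation), with Nr4a3 at 4.28 ± 0.45 and Atf3 at 3.88 ± 0.41. Of fatty acid oxidation genes 4 of 21 rose, 5 adjusted over the list alone (adjusted p = 0.00382; adjusted p = 0.821 with an estimated correlation). They included Pdk4, which holds back pyruvate oxidation (1.58 ± 0.33), and Angptl4, a lipase inhibitor (1.78 ± 0.46). Cardiac stress genes rose in 2 of 13 members in both counts (adjusted p = 0.0147; adjusted p = 0.412 with an estimated correlation), Xirp1 by 1.09 ± 0.21 and Flnc by 0.83 ± 0.14. The list call was lost without air 4 h replicate 1 (0.0568) or HCN 4 h replicate 1 (0.0659). Ptx3 rose by 3.31 ± 0.34, Agt by 2.64 ± 0.32 and Hmox1 by 2.54 ± 0.30. Among falls, the prostaglandin receptor Ptger3 fell by 2.24 ± 0.44, Tppp, which binds tubulin, by 1.59 ± 0.19, Id4, an inhibitor of transcription factors, by 1.44 ± 0.27. The glycogen-targeting subunit Ppp1r3b fell by 1.38 ± 0.25, the fibroblast transcription factor Tcf21 by 1.23 ± 0.21 and Inmt, a methyltransferase, by 1.72 ± 0.38. The actin ratio was 0.411 ± 0.0436 in HCN and 0.4 ± 0.0384 in air. Of called probe sets whose gene had others, 69% had another in the same direction at an unadjusted p under 0.05. For randomly paired probe sets it was 18%. In all, 768 probe sets rose (456 genes) and 1199 fell (847 genes), 1053 by at least 1.5-fold. Quantile normalization changed the share that rose from 39% to 51.6%. The count of 1967 was 613, 648 and 620 with 3 to 5 within-gene factors and 1208 in a fit of these groups alone.

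**Figure D4:**
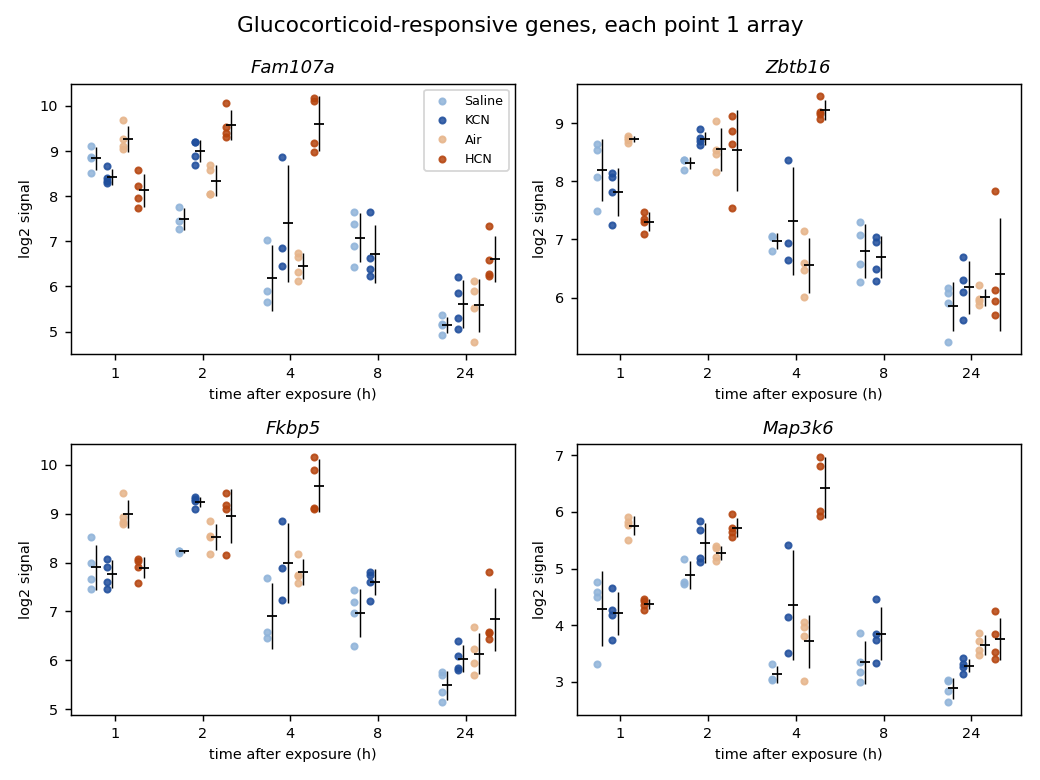
Log2 signal of the glucocorticoid-responsive genes Fam107a, Zbtb16, Fkbp5 and Map3k6 against hours after exposure, with a point per array for saline, KCN, air and HCN, and bars for the mean ± SD. In air Fam107a went from 9.27 ± 0.29 at 1 h to 5.58 ± 0.59 at 24 h, and at 4 h it read 9.61 ± 0.62 after HCN and 6.46 ± 0.29 in air.

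In HCN against air at 24 h, Lcn2, an iron-sequestering protein of the acute phase, rose by 1.91 ± 0.33, from 4.63 ± 0.57 (SD) to 6.54 ± 0.71, Agt by 1.64 ± 0.32, and Pnmt, the enzyme that makes adrenaline, by 1.35 ± 0.23. Glucocorticoid-responsive genes rose in 3 of 19 members in both counts (adjusted p = 0.0252; adjusted p = 0.994 with an estimated correlation), a call lost without air 24 h replicate 3 (0.17) or HCN 24 h replicate 3 (0.258). Atrial cardiomyocyte markers fell in 2 of 6 members in both counts (adjusted p = 0.00487; adjusted p = 0.64 with an estimated correlation), a call lost without air 24 h replicate 1 (0.0719). Gja5, a gap junction protein of atria and conduction tissue, fell by 1.497 ± 0.23. Fibroblast markers fell in 2 of 9 members in both counts (adjusted p = 0.00943; adjusted p = 0.64 with an estimated correlation), a call lost without HCN 24 h replicate 4 (0.104). Mpst fell by 0.78 ± 0.13, but for Mpst, HCN against air at 24 h, the change was 0.02909 to 0.03439 with 1 to 5 within-gene factors. The largest falls were on single probe sets: Ywhag, a 14-3-3 protein, fell by 3.07 ± 0.31, Kcnip2 by 2.95 ± 0.44, Timp2, an inhibitor of matrix proteases, by 2.87 ± 0.34 and Sec61a1, the channel of protein translocation, by 2.75 ± 0.26. They had medians of -0.23, -0.12, -0.30 and -0.21 on their other probe sets. Of called probe sets whose gene had others, 35.9% had another in the same direction at an unadjusted p under 0.05. For randomly paired ones it was 25.5%. The actin ratio was higher in HCN by 0.593 and the Gapdh ratio by 0.223 (exact permutation p = 0.0286 each; 0.0858 and 0.129 adjusted). In all, 1360 probe sets rose (963 genes) and 2474 fell (1702 genes), 1874 by at least 1.5-fold. The count of 3834 was 2533 without HCN 24 h replicate 2, 733 with the actin ratio as a covariate, and 84, 120, 155, 178 and 181 with 1 to 5 within-gene factors, and 47 of the 120 were among the 3834.

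In HCN against air averaged over the 4 times, immediate early genes (22 of 26 higher, 24 adjusted over the list alone, adjusted p = 6.43e-31), NF-kB targets (18 of 23, 19 alone, 1.78e-25) and glucocorticoid-responsive genes (17 of 19, 18 alone, 1.99e-24) were higher. In that order they had an adjusted p = 0.000181, 5.99e-06 and 0.00028 with an estimated correlation. P53 targets went both ways, with 7 of 17 higher and 3 lower in both counts (adjusted p = 0.00297; adjusted p = 0.00531 with an estimated correlation). Matrix genes rose in 6 of 15 in both counts (adjusted p = 0.000945; adjusted p = 0.525 with an estimated correlation). Atf3 rose by 3.25 ± 0.20, Ptx3 by 2.48 ± 0.17, Cxcl1 by 2.08 ± 0.16 and Egr1 by 2.05 ± 0.20, with n = 16 HCN and 16 air arrays. Agt rose by 1.98 ± 0.16, Errfi1, an inhibitor of growth factor receptors, by 1.39 ± 0.14, Hmox1 by 1.02 ± 0.15 and the basement membrane collagen Col4a1 by 0.32 ± 0.06. In all, 1979 probe sets rose and 3768 fell, 462 by at least 1.5-fold. Quantile normalization changed the share that rose from 34.4% to 46.7%. The count of 5747 was 2220 with the actin ratio as a covariate and 2412, 1358, 95, 144 and 83 with 1 to 5 within-gene factors.

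**Figure D5:**
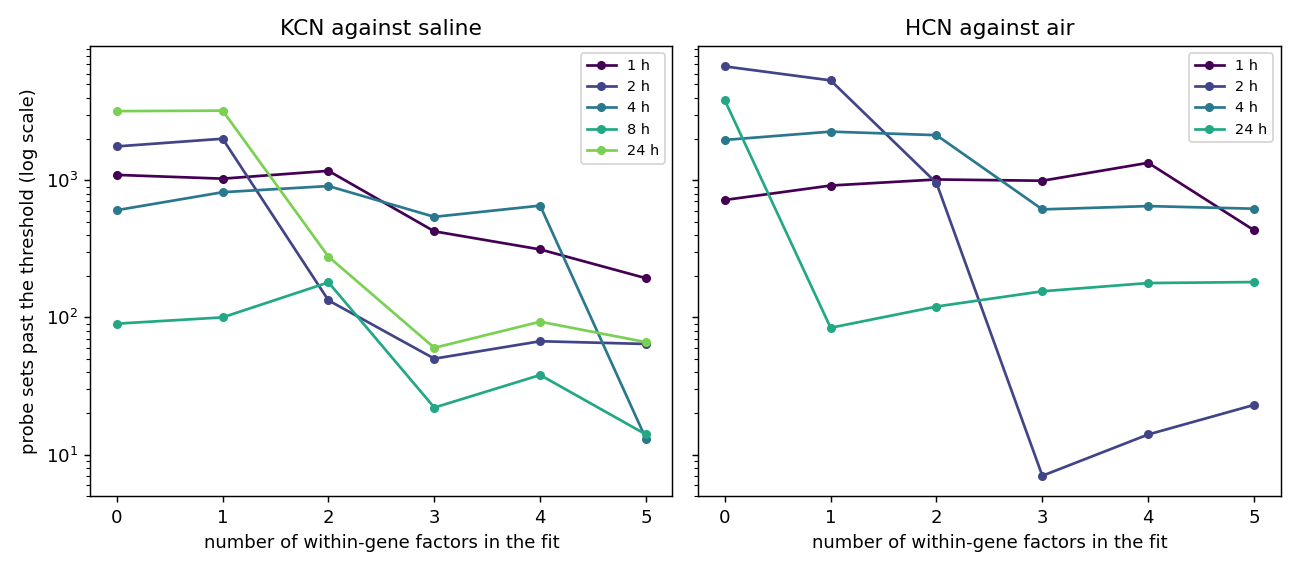
Number of changed probe sets, on a log scale, against the number of within-gene factors used as covariates, with a line per time and a panel each for KCN and HCN. At HCN 2 h the count went from 6763 with 0 factors to 7 with 3.

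The effects of HCN and KCN were subtracted from each other at each shared time, which asks whether the routes differed. In the difference between the HCN and KCN effects at 1 h, immediate early genes had 2 of 26 members with a larger effect of HCN, 10 adjusted over the list alone (median 0.79; adjusted p = 7.83e-13; adjusted p = 0.049 with an estimated correlation). NF-kB targets had 3 of 23, 6 alone (adjusted p = 5.17e-09; adjusted p = 0.029 with an estimated correlation). The effect of HCN exceeded that of KCN by 3.18 ± 0.46 for Cxcl1, 2.75 ± 0.27 for Cxcl2, 2.34 ± 0.37 for Fosb, 2.18 ± 0.38 for Nfkbiz and 1.87 ± 0.21 for Spry4, an inhibitor of growth factor signalling. Cxcl1 read 2.866 to 3.506 in saline and 3.101 to 3.582 in air, around the filter threshold of 3.23. Fosb lay below it in air (2.323 to 2.758). The sizes of their differences are therefore uncertain. NRF2 targets, which defend against oxidants, had a median difference of -0.25 with 0 of 15 past the test and 1 lower adjusted over the list alone (adjusted p = 0.000682; adjusted p = 0.0657 with an estimated correlation). Lymphocyte markers had a median of -0.90 with 0 of 8 past the test in either count (adjusted p = 0.0111; adjusted p = 0.46 with an estimated correlation, and 0.136 without air 1 h replicate 1). In hypoxia response and HIF targets, difference between the HCN and KCN effects at 1 h, 1 of 23 was higher in both counts (adjusted p = 0.0353; adjusted p = 0.262 with an estimated correlation). That call was lost without saline replicate 1 (0.0635) or 4 (0.0795), KCN replicate 3 (0.0878) or 4 (0.0517), air replicate 1 (0.0607) or 2 (0.075), or HCN replicate 4 (0.0612). Endoplasmic reticulum chaperones were lower as a list too (camera adjusted p = 0.00386). Of all lists 3 passed higher and 5 lower, and 2 passed with an estimated correlation, the immediate early genes and NF-kB targets. In all, 44 probe sets were higher in the difference and 9 lower, 52 by at least 1.5-fold. The routes differed in more than the form of cyanide, since the dose, its delivery and the normalization differed with them.

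In the difference between the HCN and KCN effects at 2 h, Cxcl1 and Ptx3 had larger effects of HCN by 2.28 ± 0.48 and 2.15 ± 0.51, and the muscle genes Xirp1 and Flnc by 1.19 ± 0.30 and 0.82 ± 0.20. Xirp1 no longer passed with the actin ratio as a covariate (1.136). Clec1b, a platelet receptor, differed by 3.02 ± 0.65 and Sppl2a by -2.17 ± 0.23, with a median of -0.0469 on its other 2 probe sets. Immediate early genes had 3 of 26 members higher, 6 adjusted over the list alone (adjusted p = 2.86e-05; adjusted p = 0.565 with an estimated correlation). NF-kB targets had 2 of 23 in both counts (adjusted p = 0.00202; adjusted p = 0.565 with an estimated correlation). Glycolysis enzymes were lower in 3 of 13, 5 alone (adjusted p = 0.00869; adjusted p = 0.606 with an estimated correlation), a call lost without HCN 2 h replicate 2 (0.0565) and a direction that turned with 3 and 4 within-gene factors. Cytochrome c oxidase subunits were lower in 4 of 19 in both counts (adjusted p = 0.0263; adjusted p = 0.565 with an estimated correlation), lost without saline 2 h replicate 3 (0.113). In all, 575 probe sets were higher and 959 lower, with 47.9% higher after quantile normalization in place of 37.5%. The count of 1534 was 903 without saline replicate 2, 954 and 656 without HCN replicates 1 and 2, and 219 without both of those. It was 260 with the actin ratio as a covariate, and 277, 386, 20, 28 and 35 with 1 to 5 within-gene factors.

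In the difference between the HCN and KCN effects at 4 h, glucocorticoid-responsive genes had larger effects of HCN in 6 of 19 members, 11 adjusted over the list alone (median 0.97; adjusted p = 9.45e-13; adjusted p = 0.0241 with an estimated correlation). NF-kB targets had larger effects in 6 of 23, 10 alone (adjusted p = 2.41e-12; adjusted p = 0.00406 with an estimated correlation). Zbtb16 differed by 2.32 ± 0.48, Ptx3 by 2.55 ± 0.53 and Nfkbia by 1.08 ± 0.23, and on the other side Tppp by -2.01 ± 0.28 and Id4 by -2.12 ± 0.42. Fam107a differed by 1.94 ± 0.51 on the probe set given for the single routes. On another probe set it differed by 2.32 ± 0.50, and by 1.91 without KCN 4 h replicate 1, where it no longer passed. In all, 173 probe sets were higher and 328 lower, with 58.2% higher after quantile normalization in place of 34.5%. The count of 501 was 303, 147 and 765 without saline replicates 1, 2 and 3, 109 and 271 without KCN replicates 1 and 3, 259 without air replicate 2 and 328 without HCN replicate 4. It was 143 with the airway level as a covariate and 866, 1013, 918, 961 and 765 with 1 to 5 within-gene factors.

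In the difference between the HCN and KCN effects at 24 h, Mpst differed by -1.46 ± 0.19, having, without covariates, risen after KCN and fallen after HCN. The probe sets with the largest differences, Kcnip2 (-4.50 ± 0.62), Gna12, a G protein subunit (-3.73 ± 0.45), Ndufab1 (3.71 ± 0.40) and Rab2a (3.44 ± 0.36), belonged to genes whose other probe sets had medians of -0.27, -1.52, -0.14 and 0.56. Glycolysis enzymes were lower in 4 of 13, and 1 was higher and 5 lower adjusted over the list alone. Fibroblast markers were lower in 3 of 9, 5 alone (adjusted p = 0.0298 for each list; adjusted p = 0.497 for each with an estimated correlation). Both calls were lost without KCN 24 h replicate 2, at 0.0746 each, and without HCN 24 h replicate 4, at 0.062 and 0.0826, and the direction of glycolysis enzymes turned with 2 to 5 within-gene factors. The actin ratio moved in opposite directions by the 2 routes at this time, by -0.405 after KCN and 0.593 after HCN. In all, 2166 probe sets were higher and 2871 lower. The count of 5037 was 808 with the actin ratio as a covariate and 589, 152, 63, 100 and 121 with 1 to 5 within-gene factors.

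The effects of both routes were also correlated across the tested probe sets, which are not independent replicates. Pearson's r was 0.332 at 1 h, 0.335 at 2 h, 0.0432 at 4 h and -0.138 at 24 h, and Spearman's rho was 0.319, 0.316, 0.101 and -0.161. At 1 h 113 probe sets rose by both routes where independence gives 5.77, and 90 fell by both where it gives 8.8 (Fisher's exact test, adjusted p = 7.02e-115 and 3.48e-64 over the 8 overlaps). At 2 h 304 rose by both (expected 77.5) and 362 fell by both (145), and at 4 h 64 rose (9.32) and 26 fell (12.5). At 24 h 34 rose by both where independence gives 92.3 and 69 fell by both (127), while 351 rose after KCN and fell after HCN (168) and 171 fell after KCN and rose after HCN (69.8). In the correlation of the KCN and HCN effects at 4 h, r was -0.046 without KCN replicate 2, -0.00773 without air replicate 3, -0.0566 without HCN replicate 1 and -0.0111 without HCN replicate 3.

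The controls were compared with each other over time within each route, which asks what the handling, the vehicle and the time of day together changed without cyanide. Glucocorticoid-responsive genes passed an F test in 16 of 19 members in the saline time course, where 40.6% of all genes passed, and in 16 of 19 in air, where 15.6% did. Fam107a went from 8.84 ± 0.25 (SD) at 1 h to 5.15 ± 0.18 at 24 h in saline (adjusted p = 2.03e-11) and from 9.27 ± 0.29 to 5.58 ± 0.59 in air (9.01e-12). Zbtb16 went from 8.19 ± 0.53 to 5.85 ± 0.42 in saline and from 8.723 ± 0.05 to 6.004 ± 0.15 in air. Fkbp5 went from 7.91 ± 0.46 to 5.49 ± 0.30 in saline and from 8.998 ± 0.29 to 6.138 ± 0.43 in air. The inhibitor of cell division Cdkn1a and the acute phase factor Cebpb were highest at 1 h, at 9.37 ± 0.59 and 10.61 ± 0.14 in saline. The early response gene Nr4a1 was 9.44 ± 0.44 at 1 h and 5.36 ± 0.55 at 4 h in saline. Tfrc, the transferrin receptor, was highest at 24 h in both courses, at 7.94 ± 0.22 in saline and 6.83 ± 0.25 in air. Scd1, a desaturase of fat synthesis, reached 6.31 ± 1.67 at 24 h in air from 4.05 ± 0.37 at 1 h. Of genes of the circadian clock and its output 9 of 17 passed in saline and 4 of 17 in air. The output gene Dbp ranged from 5.59 ± 0.77 at 1 h to 8.51 ± 0.79 at 8 h in saline (adjusted p = 0.000562). Integrated stress response genes passed in 14 of 20 in saline and 3 of 20 in air, proteasome genes in 10 of 13 and 4 of 13, endothelial markers in 7 of 10 in saline and 5 of 10 in air, and interferon-stimulated genes in 2 of 17 in saline and 0 of 17 in air. In all, 10266 probe sets (5997 genes) passed in the time course in saline controls and 4482 (2812 genes) in the time course in air controls. The counts were 491 and 999 with the replicate block. They were 3623, 2804, 2183 and 1976 with 2 to 5 within-gene factors in saline and 2525, 654 and 814 with 3 to 5 in air. The saline groups also differed in the actin ratio, from 0.422 at 2 h to 0.879 at 24 h. By the 18S control the saline 2 h group stood apart, at 11.8 ± 0.225 where the means of all other groups were 12.9 to 13.18. Its second within-gene factor was 0.301 to 0.341, also the highest of all groups. Both measures enter the saline time course and the comparison at KCN 2 h.

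Several gene groups passed in none of the 15 comparisons of cyanide with control or of the routes. The enzymes that detoxify cyanide and sulfide were closest at KCN 24 h (lowest adjusted p = 0.0752), where Tst and Mpst rose as single genes. The lowest adjusted p was 0.169 for the circadian clock, 0.111 for heat shock proteins, 0.173 for ubiquitin and proteasome genes, 0.0511 for ventricular cardiomyocyte markers, 0.0517 for endothelium, 0.0656 for thymocytes, 0.119 for erythroid cells, 0.235 for smooth muscle and pericytes, 0.243 for skeletal muscle and 0.243 for Schwann cells and nerve. A group that did not pass is not shown to be unchanged. Over the 15 comparisons 86 list results passed, of which 19 also passed with an estimated correlation, and 42 were lost without at least 1 array.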

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

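Of the tests weighed here, only the one for airway tissue carried over with the heart was written before its result was seen; the other tests of explanations were chosen only after the result was seen.

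Several single arrays stood apart from the other 3 of their group. This was so in 15 of 378 checks (3.97%), each of 1 gene or control measure in 1 group of 4 arrays. Chance gives about 1 in 20, so these are no more than chance would give. Agt read 6.343 in KCN 8 h replicate 3 and 6.806 to 6.884 in the others. Pkm read 10.74 and Mmp2 9.43 in KCN 24 h replicate 2, against 10.51 to 10.53 and 8.971 to 9.047. In air at 1 h, Egr1 read 7.782 in replicate 1 (others 6.787 to 6.915), Fosb 2.323 in replicate 3 (2.723 to 2.758) and Pmaip1 3.329 in replicate 2 (2.73 to 2.815). In HCN at 1 h, Ccn1 read 10.88 in replicate 3 (10.71 to 10.73), Nfkbia 11.02 in replicate 4 (10.83 to 10.86) and Gadd45g 9.555 in replicate 2 (9.169 to 9.207). Nfkbia read 9.058 in air 2 h replicate 1 (8.72 to 8.76). S100a9 read 7.909 and S100a8 6.601 in HCN 4 h replicate 4 (8.66 to 8.723 and 7.639 to 7.719), and S100a9 6.421 in air 4 h replicate 2 (5.656 to 5.724). Gna12 read 6.425 and Mpst 7.803 in HCN 24 h replicate 4 (5.15 to 5.175 and 7.126 to 7.206).

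The effects of the routes differed, by a test of the difference itself, in 53 probe sets at 1 h, 1534 at 2 h, 501 at 4 h and 5037 at 24 h. In log2 units, HCN minus KCN, the differences at 1 h were 3.18 for Cxcl1, 2.753 for Cxcl2, 2.336 for Fosb, 2.184 for Nfkbiz, 2.191 for Nfe2l2 (with -0.19 on its other probe set), 1.872 for Spry4, 1.482 for Ier2 and 1.131 for Adm. Ier2 no longer passed without KCN 1 h replicate 1 (1.34) or replicate 4 (1.14), and Adm without 9 of the 16 arrays or with the actin ratio as a covariate (1.073). At 2 h they were 2.275 for Cxcl1, 2.148 for Ptx3, 3.024 for Clec1b, 2.176 for Ctla2a, -2.173 for Sppl2a (with a median of -0.0469 on its other 2 probe sets), 0.8235 for Flnc, 1.187 for Xirp1 and 2.229 for Egr1, and Egr1 no longer passed without saline 2 h replicate 3 (1.81) or HCN 2 h replicate 2 (1.94). Egr1 also no longer passed with the actin ratio (1.799) or 2 within-gene factors (1.661), and Xirp1 with the actin ratio (1.136). With 3 factors only Sppl2a of these 8 still passed, and the smallest of the others was 0.5696 for Xirp1, difference between the HCN and KCN effects at 2 h. At 4 h they were 2.546 for Ptx3, 2.322 for Fam107a (1.94 on the probe set plotted in the report), 2.317 for Zbtb16, 1.905 for Hmox1, 1.86 for Ccl2, 1.811 for Ccl7, 1.764 for Socs3, 1.075 for Nfkbia, -2.841 for Ptger3, -2.123 for Id4 and -2.013 for Tppp. Of these, Fam107a and Ptger3 no longer passed without KCN 4 h replicate 1 (Fam107a at 1.91, and Ptger3, difference between the HCN and KCN effects at 4 h, at -2.86). The others, Hmox1, Ccl7, Socs3 and Ccl2, no longer passed without 3, 3, 7 and 11 of the 14 arrays. At 24 h they were 3.706 for Ndufab1, 3.439 for Rab2a, -4.498 for Kcnip2, -3.729 for Gna12, -1.457 for Mpst and -1.049 for Tst, which no longer passed without 7 of the 16 arrays. With 2 factors Kcnip2 (-0.3065), Gna12 (-0.7139), Mpst (-0.3159) and Tst (-1.486) no longer passed.

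The many falls at HCN 2 h and HCN 24 h may reflect lower signal from the 5' part of transcripts in these RNAs. Over the 61 arrays outside the groups compared, with the group means removed, the mean of the probe sets that fell at HCN 2 h went with the actin 3' to 5' ratio at r = -0.652 (rho = -0.661, permutation p = 1e-05, the smallest they can give, and 2e-05; r = -0.602 without the 2 arrays farthest from the median), and that of the probe sets that fell at HCN 24 h at r = -0.9 (rho = -0.827, permutation p = 1e-05 each; r = -0.845 without them), while the probe sets that rose went with it at HCN 24 h (r = 0.787, rho = 0.659, permutation p = 1e-05 and 9e-05) and not past the test at HCN 2 h (r = 0.162, rho = 0.19, permutation p = 0.198 and 0.189). The other probe sets of the genes that fell at HCN 24 h had a median of -0.0156 of the change of the called ones (95% interval -0.0312 to 0.00345), which argues against falls of whole transcripts, though called probe sets are selected for large changes, which lowers this share everywhere. It was 0.248 at HCN 2 h (0.221 to 0.27), which leaves both explanations open there, and 0.627 for falls at HCN 4 h, while for rises it was also low at HCN 24 h (0.0607, 0.01 to 0.123) and HCN 2 h (0.203, 0.158 to 0.249), so that the same doubt holds for rises, and 0.74 at HCN 4 h. The intervals of these shares come from resampling probe sets, which are not independent. They leave out the spread between arrays and are likely too narrow. Whether cyanide itself changed RNA stability or transcript ends, or the samples were handled differently, was not tested.

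The intervals in this paragraph come from resampling probe sets, which are not independent. They leave out the spread between arrays and are likely too narrow, so the readings rest on the medians. The falls at KCN 24 h lie mostly on the control side. In the median over these probe sets 78.3% of the change (76.6 to 80.4) was a departure of the saline 24 h arrays from the other saline groups, which suggests that the saline 24 h arrays stand apart, and the other probe sets of these genes had 0.326 of the change (0.295 to 0.356), which leaves a fall of the transcripts open. For the falls at KCN 1 h the share on the saline side was 54.2% (51 to 56.1), which does not decide, and the other probe sets had 0.149 of the change (0.0936 to 0.205), which argues against falls of whole transcripts. The actin ratio was 0.841, 0.859 and 0.879 in saline at 1, 4 and 24 h and 0.422 and 0.454 at 2 and 8 h, so that by this ratio the saline 24 h arrays were not apart from those at 1 and 4 h. The share of the other probe sets was also low for rises at KCN 2 h (0.181, 0.113 to 0.233) and falls at KCN 4 h (0.118, 0.0536 to 0.192), and time of day in the control mice was not told apart from time since handling, since both move with the hour of harvest.

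The airway transcripts that were higher at KCN 1 h may come from airway epithelium carried over with the heart. Over the 61 arrays outside that comparison, with group means removed, 10 other airway genes on a list written before the test had a median r of 0.764 with Scgb1a1 and Bpifa1 (0.393 to 0.987), against a 95th percentile of 0.097 for random lists (permutation p = 1e-04, the smallest they can give). Cartilage and alveolar lists had medians of 0.221 (permutation p = 2e-04) and 0.374 (permutation p = 3e-04), and a thyroid list -0.0213 (permutation p = 0.532). None of the 10 is on the list of lung epithelium markers, and Scgb3a1, Scgb3a2 and Sec14l3 had been taken off the airway list because they were seen to rise at KCN 1 h. An induction by cyanide stays open, since 15 of 19 KCN and 3 of 18 saline arrays read Scgb1a1 above 8 (Fisher's exact test, p = 0.000234), although 13 of 16 air arrays, without cyanide, did so as well, as did 12 of 16 HCN arrays (p = 1).

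The real grouping gave more changed probe sets than any other split tried in these comparisons. They were KCN 1 h (1094, highest other split 47), KCN 2 h (1765, 1163), KCN 24 h (3191, 105), HCN 1 h (718, 68), HCN 2 h (6763, 2872), HCN 4 h (1967, 274) and HCN 24 h (3834, 1344). They were also the averages of KCN (2547, 735) and HCN (5747, 1057) and the time courses in saline (10266, 2775) and air (4482, 873). The differences at 1 h (53, 21), 2 h (1534, 1372), 4 h (501, 356) and 24 h (5037, 213) were tested by shuffling residuals of a fit without the difference. With 35 splits at a single time the smallest share is 0.0286, and with 100 in the rest it is 0.01. These shares were not adjusted over the comparisons, so chance is made less likely but is not excluded. The splits at KCN 4 h were too few for such a test (605, highest other 7). At KCN 8 h 5 of 35 splits gave as many as the real 90, with up to 743, so that chance cannot be excluded. The split with 743 set replicates 1 and 2 of both groups against the others. It points to a structure of the samples other than the exposure. A count above those of all other splits does not tell an effect of cyanide from a difference in RNA quality between the same groups.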

How the results depend on the processing

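The covariates, the setting of 1 probe set per gene and the leaving out of the 2 HCN 2 h arrays of highest actin ratio were chosen only after the data were seen; the other settings were planned. Median centring, a stricter filter and eBayes without the trend kept all 17 counts within 1.5 times. Of 276 gene results, 198 kept their direction and side of the threshold in all planned settings with leave-one-out, 100 did so in every setting, and 64 were lost without at least 1 array. Of 86 list results these numbers were 18, 16 and 42. By setting, 271 of 276 gene results were kept under quantile normalization, 273 under median centring, 262 without a filter, 258 with the replicate block, 145 of 191 in fits of only 2 groups, 259 with the actin ratio, 247 with the airway level, and 252, 232, 142, 144 and 114 with 1 to 5 within-gene factors. At every number of factors 10 of 27 gene results were kept at KCN 1 h, 3 of 21 at 2 h, 0 of 14 at 4 h, 1 of 13 at 8 h, 3 of 16 at 24 h and 1 of 14 in the KCN average. These were 23 of 27 at HCN 1 h, 0 of 25 at 2 h, 21 of 35 at 4 h, 4 of 13 at 24 h and 8 of 14 in the HCN average. Lists were kept in 79 of 86 under quantile normalization, 84 with the replicate block, 64 with the probe set of highest variance and 19 with an estimated correlation. The cause of the moves listed here was not tested, except that fits of only 2 groups have fewer residual degrees of freedom and that 1 probe set per gene tests fewer probe sets. The alternative without an offset was not run. The spike-in cre lay 5.09 above bioB, and probe sets below the filter were tested only in the setting without it.

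These counts moved by more than 1.5 times under planned settings, with names that hold for the rest of this part. The results are KCN against saline at 1 h, KCN against saline at 2 h, KCN against saline at 4 h, KCN against saline at 8 h, KCN against saline at 24 h, KCN against saline averaged over the 5 times, HCN against air at 1 h, HCN against air at 2 h, HCN against air at 4 h, HCN against air at 24 h, HCN against air averaged over the 4 times, time course in saline controls and time course in air controls. Quantile normalization gave 916 at KCN 4 h, and no filter gave 50 at KCN 8 h. The replicate block gave 918 at KCN 2 h, 42 at KCN 8 h, 491 in the saline course and 999 in the air course. Over 34 pairs of a cyanide and a control array of equal number, the correlations ran from -0.142 to 0.318. In 0 comparisons were all above 0.1, and in 13 pairs the cyanide array correlated best with the control of its own number. A structure shared by replicate number is not ruled out, and these pairs do not cover the time courses. Separate fits per route gave 16 at KCN 8 h. Limma fits of only 2 groups gave 544 at KCN 2 h, 29 at KCN 4 h, 0 at KCN 8 h (1768 at an unadjusted p under 0.05), 451 at HCN 1 h, 1934 at HCN 2 h and 1208 at HCN 4 h. Adjustment over 9 contrasts gave 1161 at KCN 4 h, 614 at KCN 8 h and 1116 at HCN 1 h. A minimum of 1.5-fold gave 475, 1140, 343, 48 and 1085 at KCN 1, 2, 4, 8 and 24 h, 447, 2787, 1053 and 1874 at HCN 1, 2, 4 and 24 h, and 227 and 462 in the KCN and HCN averages. Leaving out each array gave 573 to 975 at KCN 1 h, 871 to 1918 at KCN 2 h, 56 to 947 at KCN 4 h, 3 to 223 at KCN 8 h, 1829 to 2771 at KCN 24 h, 474 to 647 at HCN 1 h and 2533 to 4789 at HCN 24 h. For cell cycle, KCN against saline at 2 h, the adjusted p ran from 5.6e-06 to 0.931, with the direction turned at 0.931.

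With the actin ratio as a covariate, HCN against air at 2 h gave 3016, HCN against air at 24 h 733, KCN against saline averaged over the 5 times 1552 and HCN against air averaged over the 4 times 2220. With 1 within-gene factor the last 3 gave 84, 1532 and 2412. With 2 factors KCN against saline at 2 h gave 133, KCN against saline at 8 h 180, KCN against saline at 24 h 277, HCN 2 h 955, HCN 24 h 120, the HCN average 1358 and the time course in saline controls 3623. With 3 factors KCN against saline at 1 h gave 424, KCN 2 h 50, KCN 8 h 22, KCN 24 h 60, HCN 2 h 7, HCN against air at 4 h 613, HCN 24 h 155, the averages 25 (KCN) and 95 (HCN), and the saline and air courses 2804 and 2525. With 4 factors KCN gave 313, 67, 38 and 93 at 1, 2, 8 and 24 h, HCN against air at 1 h gave 1340, and HCN 2, 4 and 24 h gave 14, 648 and 178. The averages then gave 40 and 144 and the courses 2183 and 654. With 5 factors KCN gave 193, 64, 13, 14 and 66 at 1, 2, 4, 8 and 24 h, HCN gave 432, 23, 620 and 181 at 1, 2, 4 and 24 h, the averages 31 and 83, and the time course in saline controls and the time course in air controls 1976 and 814. With 1 probe set per gene KCN gave 549, 789, 303 and 1799 at 1, 2, 4 and 24 h, HCN gave 376, 3161, 1192 and 1038 at 1, 2, 4 and 24 h, the averages 1287 and 2481 and the courses 5175 and 1890. The airway level gave 229 for KCN against saline at 4 h and 1154 for the KCN average. Without the 2 arrays of highest actin ratio HCN 2 h gave 3278.

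For the difference between the HCN and KCN effects at 1 h, 2 factors gave 88 and 1 probe set per gene gave 13. For the difference between the HCN and KCN effects at 2 h, the actin ratio gave 260, factors 1 to 5 gave 277, 386, 20, 28 and 35, 1 probe set per gene 539, leaving out both arrays of highest ratio 219, and leaving out each array 656 to 2206. For the difference between the HCN and KCN effects at 4 h, factors 1 to 5 gave 866, 1013, 918, 961 and 765, 1 probe set per gene 307, the airway level 143, and leaving out each array 109 to 765. For the difference between the HCN and KCN effects at 24 h, the actin ratio gave 808, factors 1 to 5 gave 589, 152, 63, 100 and 121, and 1 probe set per gene 2101. For the correlation of the KCN and HCN effects at 4 h, 3 and 4 factors gave -0.0513 and -0.0555, 1 probe set per gene -0.036, and leaving out each array -0.0566 to 0.121. For the correlation of the KCN and HCN effects at 24 h, 1 and 2 factors gave -0.271 and -0.246.

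Some genes turned direction under settings added later. For Mpst, HCN against air at 24 h, the log2 change was 0.03439, 0.03261, 0.03118, 0.02909 and 0.03097 with 1 to 5 factors. For Kcnip2, HCN against air at 2 h, it was 0.3032, 1.019, 0.9975 and 0.9293 with 2 to 5, and for Gapdh, HCN against air at 2 h, 0.08056, 0.1146 and 0.1129 with 3 to 5. For S100a8, HCN against air at 2 h, it was -1.797, -1.782 and -1.905 with 3 to 5. Akt1, HCN against air at 2 h, had 0.08854 with 3, and Klc1, HCN against air at 2 h, 0.0007891 with 4. Bpifa1, KCN against saline at 1 h, had -0.08099 with the airway level, which is made from Bpifa1 itself and so removes its change by construction. Lists that turned direction are given by their adjusted p. For glycolysis enzymes, HCN against air at 2 h, it was 0.641, 0.0305, 0.0514 and 0.0189 with 2 to 5 factors. For glycolysis enzymes, HCN against air averaged over the 4 times, it was 0.297, 0.0129, 0.00856 and 0.000326. For glycolysis enzymes, difference between the HCN and KCN effects at 24 h, it was 0.338, 0.751, 0.696 and 0.735. For glycolysis enzymes, difference between the HCN and KCN effects at 2 h, it was 0.737 and 0.951 with 3 and 4. For extracellular matrix and fibrosis, KCN against saline at 24 h, it was 0.856, 0.874 and 0.942 with 3 to 5. For extracellular matrix and fibrosis, HCN against air at 2 h, it was 0.984 with 4, and for extracellular matrix and fibrosis, difference between the HCN and KCN effects at 2 h, 0.45 and 0.459 with 4 and 5. For markers: neutrophil, HCN against air at 2 h, it was 0.357, 0.376 and 0.406 with 3 to 5. For markers: neutrophil, HCN against air averaged over the 4 times, it was 0.464, 0.451 and 0.507. For NRF2 and oxidative stress targets, KCN against saline averaged over the 5 times, it was 0.517, 0.55 and 0.24.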

Other observations

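This part gives values from the same fit and runs no test of an explanation, and its genes were picked after their values were seen.

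Agt, the precursor of angiotensin, rose after HCN by 2.19 ± 0.32 (SE) at 2 h, 2.64 ± 0.32 at 4 h and 1.64 ± 0.32 at 24 h. Gfod1 rose by 2.40 ± 0.25 at HCN 4 h and 1.32 ± 0.25 at HCN 24 h on 1 probe set, with medians of 0.01 and 0.05 on its other probe sets. Nfe2l2, the transcription factor NRF2, rose by 1.54 ± 0.13 in the HCN average on 1 probe set and had -0.15 on the other.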
